A study of Mus musculus with 4 samples.

How the data were processed

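RNA sequencing of mouse T helper 17 (Th17) cells was analysed from 4 libraries. Per the labels, all 4 hold total RNA of primary Th17 cells of strain C57BL/6NJ, and the linked culture protocol is for the differentiation of CD4 T cells. Th17 cells are CD4 T cells that secrete IL-17. The assay label reads total RNA-seq, while the linked library protocol names selection of poly(A)-tailed RNA. The libraries carry biological replicate numbers 1 to 4 and 1 shared donor label, and sex and age are not given. They form a single group with no contrast, so each comparison sets genes, gene lists or libraries of that group side by side. Since the labels do not say whether they came from separate animals or cultures, p-values measure the spread between these samples only, and part of that spread may be technical.

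The authors deposited, per the file headers, raw fragment counts per gene made with featureCounts 1.4.6-p4 on paired reads. Both ends had to be mapped, and strand was read with option 2, the reverse-stranded setting, so antisense partners are counted apart. The file headers name the GENCODE M13 gene models, and the labels name the mm10 genome build. The aligner is not given in the sources used here beyond a hint in the names of the alignments. The counting command held neither the option for multi-mapping fragments nor the option for fragments that overlap 2 genes, so such fragments were left uncounted. The output name of the counting command carries 48 hours, which the labels do not repeat. The deposited tables also give each gene's exon length in bases. Every file lists 50600 genes, of which 28261 had no count in any library. Gene symbols and biotypes came from GENCODE M21, which is on the same build, matched by gene ID without version for 50376 genes, of which 45737 also matched in version. Coordinates are those of the deposited files.

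Totals were 28555677 counts in replicate 1, 36998648 in replicate 2, 58104663 in replicate 3 and 42896684 in replicate 4. A count of 0 allows a level of up to 3 counts, which is 0.105 CPM (counts scaled to the library total) in replicate 1, 0.0811 in replicate 2, 0.0516 in replicate 3 and 0.0699 in replicate 4. Such floors and the intervals given for shares and for ratios of pooled counts cover counting error only.

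TPM, which scales counts by exon length and then to the sum of the library, was computed here from the counts and exon lengths the authors deposited. The design had assumed estimated counts and TPM in the files. Since the files hold whole-number counts, TPM was derived instead, and alternatives based on posterior means could not be run. Levels are means with SD over the 4 libraries. A protein-coding gene was called detected at 1 TPM or more in every library. Fixed gene pairs were compared within each library as log2((TPM + 0.1)/(TPM + 0.1)) with an exact two-sided sign-flip test, which with 4 libraries has 16 sign patterns, of which at least 2 are as extreme as the one observed. For 33 fixed lists, the median log2(mean TPM + 0.1) was placed among 10000 random lists of the same size from protein-coding genes with a mean TPM of at least 0.1.

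Variation between libraries was measured on counts with edgeR 4.0.16 in R 4.3.3, with TMM scaling and its default filter on low counts. With a single group that filter asks for the level in every library. It left 12434 genes, and TMM factors lay between 0.997 and 1.01. The spread is the square root of edgeR's common dispersion, the biological coefficient of variation (BCV). A gene was called variable when the Poisson deviance of its counts (chi-square, 3 degrees of freedom) had a Benjamini-Hochberg adjusted p under 0.05 and its highest CPM was at least 2 times its lowest, with a prior count of 0.5. A stricter test used the negative binomial deviance at the trended dispersion, with the same 2-fold ratio unless stated. For lists with at least 4 tested members (23 of 33), the median SD of log2 CPM (prior count 2) and the median shift of each library from the genes' means were set against 10000 random lists matched on mean log2 CPM in 20 bins. Those p-values are two-sided, adjusted over 23 lists or 92 combinations of list and library. List members are correlated with each other, so these p-values are too small and describe the libraries only. Alternatives were DESeq2 1.42.0 size factors and gene-wise dispersions, other thresholds, pseudocounts and prior counts, no filter, CPM in place of TPM, and each replicate left out. Leaving out genes of chromosomes X and Y, or mitochondrial genes, was added after the data were seen.

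The tests were checked on simulated counts of the 12434 genes. With noise at the trended dispersion and no changed gene, the Poisson test called 101 genes, the stricter test called 0, and a BCV of 0.0504 was recovered for a median of 0.0563 put in. Of genes changed in 1 library, the Poisson test found 88% at 2-fold and 98% at 3-, 4- and 8-fold, and the stricter test 78% at 2-fold, 92% at 3-fold and 98% at 4- and 8-fold. Among 200 random lists of 15 genes, 6.5% had an unadjusted list p under 0.05, and 94% of 50 lists with SDs multiplied by 2 were found. To measure sequence shared between genes, each 100-base window of a gene's longest GENCODE M21 transcript was searched for in the transcripts of all other genes on either strand.

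Genes named below follow a rule set before the data were examined: members of the fixed pairs, up to 4 members with the highest mean TPM per list, the 10 protein-coding genes with the highest mean TPM, up to 10 variable protein-coding genes with a mean TPM of at least 5, and the 4 members with the largest change in a called list. Other genes are said to be chosen after their values were seen. Some genes and pairs that the rule names are not reported here.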

Results

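Gene expression was measured by RNA sequencing in 4 replicate libraries of mouse Th17 cells, a CD4 T cell type that secretes IL-17. All 4 libraries belong to the same group, so the values describe this cell type and the spread between its replicates. Library totals ranged from 28555677 to 58104663 fragment counts. The number of genes with at least 1 count ranged from 17983 in replicate 1 to 19433 in replicate 3. Protein-coding genes at 1 TPM or more in every library numbered 10223, and a threshold of 5 TPM left 8813.

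By TPM of the fragments that were counted, the gene with the highest mean level among protein-coding genes was Il17f, which encodes a lineage cytokine of Th17 cells, at 11569 ± 117 TPM (SD, n = 4). It lay above Rplp1 (10734 ± 265), a ribosomal stalk protein, Eef1a1 (10714 ± 318), a translation elongation factor, and Actb (7518 ± 267), cytoskeletal actin. The other members of the 10 highest were mt-Co1, Rpl8, Hsp90ab1, mt-Nd1, Rplp0 and Rpl4, between 5019.7 and 7079 TPM. Fragments shared between genes were not counted, and what this took from Rplp1, Eef1a1 and Actb was not measured, so the order among the highest genes is uncertain. Il17f (ENSMUSG00000041872.9) spans 20777146 to 20790617 on the minus strand of chromosome 1 in mm10, and Il17a (ENSMUSG00000025929.4) spans 20730905 to 20734496 on the plus strand of the same chromosome. Il17a reached 4436 ± 179 TPM and was below Il17f in 4 of 4 libraries, with a log2 ratio of -1.38 ± 0.05.

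The first comparison asked how the Th17 lineage genes stood against those of other T helper lineages within each library. The Th17 cytokine genes Il17f and Il17a stood far above Ifng of Th1 cells and Il4 of Th2 cells. The lineage factors of other helper cells were low: Tbx21 of Th1 cells was at 10.9 ± 1.36 TPM (SD, n = 4), Gata3 of Th2 cells at 2.34 ± 0.389, Foxp3 of regulatory T cells at 5.25 ± 1.18 and Bcl6 of follicular helper T cells at 13.4 ± 1.27. Rora, which encodes a nuclear receptor of Th17 cells, was at 43.9 ± 1.75.

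Among cytokines, Il17a exceeded the Th17 cytokine Il22 (11.5 ± 2.14 TPM) by a log2 ratio of 8.59 ± 0.28 and the anti-inflammatory cytokine Il10 (126 ± 12.2 TPM) by 5.14 ± 0.14. The Th1 cytokine Ifng had 2, 1, 1 and 0 counts in replicates 1 to 4, a level at or under the floor of 3 counts. The Th2 cytokine Il4 had 2, 22, 28 and 9 counts, or 0.92 ± 0.656 TPM. With the pseudocount, Il17a exceeded Ifng by a log2 ratio of 14.74 ± 0.59 and Il4 by 12.39 ± 1.21. From counts pooled over the 4 libraries and scaled by gene length, the ratio to Ifng was 71233 (exact Poisson 95% interval 27821 to 261436) and that to Il4 was 4426 (3445 to 5786). These intervals cover counting error only and not the spread between libraries: with a floor of 3 counts, the ratio to Il4 ranged from 2746 to 16151 in single libraries. Il23r, the IL-23 receptor (31.8 ± 2.02 TPM), exceeded the IL-12 receptor subunit Il12rb2 (14.1 ± 1.63) by 1.17 ± 0.15. Ccr6, the receptor for CCL20 (163 ± 8.63), exceeded Cxcr3, a chemokine receptor of Th1 cells (24.6 ± 3.97), by 2.74 ± 0.28. Maf, a transcription factor that drives Il10 (139 ± 7.47), exceeded Csf2, which encodes GM-CSF (5.35 ± 0.609), by 4.68 ± 0.23.

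Identity and metabolism pairs had clear orders too. Cd4 was at 346 ± 16.1 TPM, while Cd8a had 0, 2, 7 and 4 counts, and the log2 ratio was 11.12 ± 0.48 (pooled ratio 4836, exact Poisson 95% interval 2828 to 9082, counting error only). Cd3e, a chain of the T cell receptor complex, was at 107 ± 1.2 TPM. The macrophage gene Lyz2 had 0 counts in every library, so Cd3e was at least 396-fold higher with a floor of 3 counts per library. Ldha, lactate dehydrogenase (3203 ± 96.9 TPM), exceeded the glucose transporter Slc2a1 (138 ± 3.23) by 4.54 ± 0.02. Tcf7, a factor of naive and memory T cells (317 ± 3.53), exceeded the proliferation gene Mki67 (249.8 ± 7.22) by 0.35 ± 0.03. Every pair given here kept its direction in 4 of 4 libraries, each with 2 of 16 sign patterns as extreme, an exact two-sided p of 0.12 when rounded and the smallest that 4 libraries allow. Without length normalisation, the order of Tcf7 and the longer Mki67 turned to a log2 ratio of -1.59 in CPM.

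**Figure D1:**
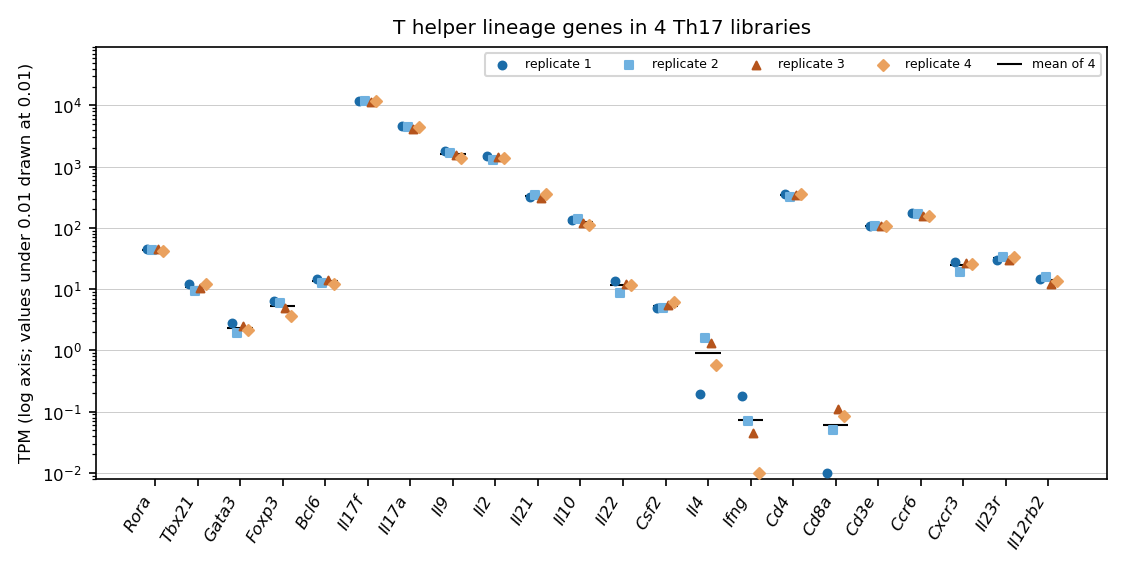
TPM (log axis) of T helper lineage genes in each of the 4 Th17 libraries, with a bar at the mean of 4; values under 0.01 are drawn at 0.01. Il17f (11569) and Il17a (4436) stand at the top, Tbx21, Gata3, Foxp3 and Bcl6 lie between 2.34 and 13.4, and Ifng (0.0737) lies near the floor.

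The second comparison placed each fixed gene list in the transcriptome, as the percentile of its median among 10000 random lists. Of 33 lists, 13 were at or above the 95th percentile. Th17 transcription factors stood at 99.98, with all 12 members at 1 TPM or more. They were led by Irf4 (813 ± 20.2 TPM, SD, n = 4) and Batf (439.5 ± 22.7), pioneer factors of Th17 differentiation, Hif1a (315 ± 10.7) and Stat3 (211 ± 6.95). Th17 cytokines and receptors stood at 100, led after Il17f and Il17a by the chemokine Ccl20 (939.6 ± 37.5) and by Il21 (333 ± 19.1).

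Lists that divide Th17 cells by their ability to cause autoimmune disease stood apart. The non-pathogenic list was at 99.34, with 7 of 7 members at 1 TPM or more. It was led by Il9 (1595 ± 174 TPM), Maf, Ahr (126 ± 4.59), a ligand-activated factor, and Il10. The pathogenic list was at 17.72, with 13 of 15 members at 1 TPM or more and a median of 11.5 TPM. Its highest members were the chemokines Ccl4 (99 ± 10.2) and Ccl3 (54.6 ± 5.01), the inhibitory receptor Lag3 (40.4 ± 3.19) and the costimulator Icos (39.2 ± 1.3). Gzmb (0.0656 ± 0.0531) and Ccl5 (0.0585 ± 0.0415), both chosen after their values were seen, were its lowest. The difference between these lists was not tested. They also share members with other lists, so the percentiles are not separate evidence. Maf, Ahr and Ikzf3 are also in the Th17 transcription factor list. Of the pathogenic list, Il22 is also among Th17 cytokines and receptors, and Tbx21 and Stat4 are among Th1 genes.

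Lists of other helper lineages stood below the non-pathogenic list, while the follicular helper list stood above the pathogenic one. Single members within them were high. Th1 genes stood at 17.39, with Il12rb1 (162 ± 6.33 TPM), Runx3 (90.8 ± 3.89) and Cxcr3 among the highest members. Th2 genes stood at 0.19, with Stat6 (191 ± 3.84), Ccr8 (145 ± 19.2) and Ccr4 (102 ± 5.43) far above Gata3. Regulatory T cell genes stood at 8.11, led by the activation-linked genes Ctla4 (1907 ± 82.9), Il2ra (1538 ± 29.4) and Tnfrsf18 (134 ± 6.71), and then by Nt5e (34.6 ± 2.54). Follicular helper genes stood at 80.79, with Pdcd1 (556 ± 21.9), Il21, Btla (134 ± 6.73) and Cxcr5 (41.5 ± 4). Naive T cell genes stood at 91.29, with Tcf7, Ccr7 (252 ± 21), Bach2 (184 ± 6.22) and Satb1 (123 ± 2.3) high. Klf2, a factor of resting T cells chosen after its value was seen, was under 1 TPM (0.465 ± 0.043).

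Genes of T cell signalling, growth and metabolism were high. T cell receptor complex and signalling genes stood at 100, led by Cd5 (1614 ± 4.88 TPM), Lck (844 ± 26.5), Trac (839.6 ± 31.5) and Lat (593 ± 19.8). T cell activation genes stood at 99.99, led by Ctla4, the growth cytokine Il2 (1407 ± 84.6), Tnfrsf4 (923 ± 53.4) and Tfrc (868 ± 17.7). The cell cycle list stood at 100, with Rrm2 (1019 ± 17.1), Mcm3 (553 ± 15.6), Pcna (552 ± 19) and Cdc20 (457 ± 10.6). Glycolysis stood at 100 with Ldha, Pkm (1822 ± 38.6), Gapdh (1383 ± 102) and Aldoa (1039 ± 19.4), and ribosomal proteins at 100 with Rpl8 (6634 ± 129), Rplp0 (5850.5 ± 95.3), Rpl4 (5019.7 ± 91.9) and Rps2 (4337 ± 126), the last of them uncertain because Rps2 shares 58.5% of its 100-base windows with another gene. Cholesterol synthesis stood at 96.85, led by Cyp51 (221 ± 5.55) and Hmgcs1 (178 ± 1.68).

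The pathways of the cytokines used to induce Th17 cells were high as well. The TGF-beta list stood at 95.82, led by Ski (185 ± 4.6 TPM), Tgfb1 (144 ± 6.76), Tgfbr1 (84.9 ± 9.17) and Skil (83.9 ± 3.67). The IL-6 and STAT3 list stood at 99.47, led by Pim1 (237 ± 11.8), Stat3, Jak2 (184 ± 5.57) and Jak1 (144 ± 1.7). Interferon-stimulated genes stood at 0, with Bst2 high (291 ± 18.8), Stat2 at 10.3 ± 0.214, Isg15 at 1.57 ± 0.315 and 8 of 12 members under 1 TPM. Immediate early and heat shock genes stood at 19.99. Junb (1054 ± 51.9), Ier2 (386 ± 17.7), Jun (74.9 ± 3.01) and Egr1 (51.6 ± 2.84) were its highest members. Against a background of genes at a mean TPM of at least 1, cholesterol synthesis fell under the 95th percentile (89.88), and so did TGF-beta (91.12). With CPM in place of TPM, replication-independent histones (91.99) and mitochondrial oxidative phosphorylation (24.17) did so, and naive T cell genes passed it (99.59). Low lists moved as well: against the background of at least 1 TPM, pathogenic Th17 genes stood at 3.04, Th1 genes at 2.77, regulatory T cell genes at 0.52 and immediate early genes at 4. With CPM, pathogenic Th17 genes stood at 1.97 and immediate early genes at 8.57, while regulatory T cell genes moved up to 24.04.

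**Figure D2:**
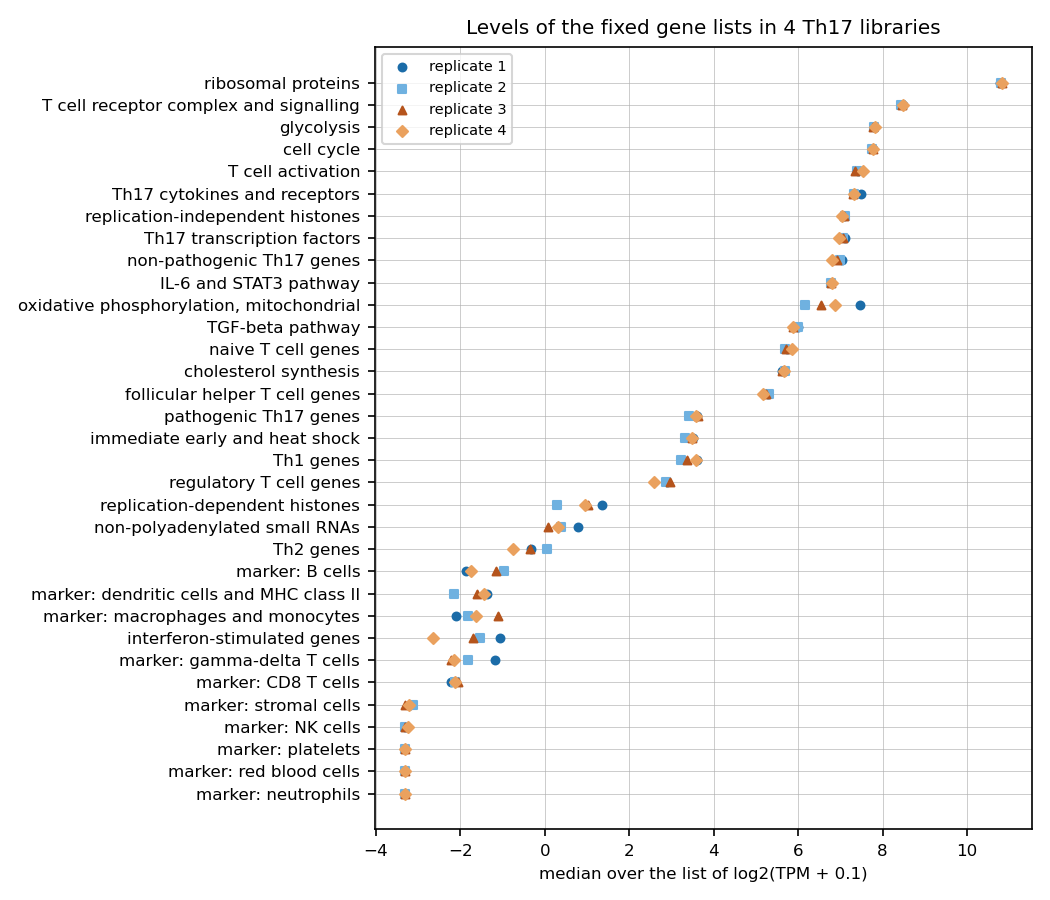
Median over each fixed list of log2(TPM + 0.1), 1 point per library. Ribosomal proteins, T cell receptor genes, glycolysis and cell cycle genes are at the top, and all 10 marker lists of other cell types have medians under 0 in every library.

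Markers of other cell types were low. All 10 marker lists were at or under the 0.03rd percentile: gamma-delta T cells at 0.03, dendritic cells at 0.02, B cells at 0.01, and CD8 T cells, NK cells, macrophages and monocytes, neutrophils, red blood cells, platelets and stromal cells at 0. Single members stood above the rest of their lists. The immunoglobulin constant genes Igkc (73.4 ± 14.2 TPM, SD, n = 4) and Ighm (19.1 ± 2.25) were present while Cd79b (0.62 ± 0.21) and Ebf1 (0.877 ± 0.0798) were under 1 TPM. Cd8b1 was at 10.2 ± 1.07 and Crtam at 2.63 ± 0.163, with Prf1 at 0.241 ± 0.087. The invariant chain gene Cd74 was at 29.7 ± 1.67, against H2-Ab1 at 1.45 ± 0.0611, H2-Eb1 at 1.03 ± 0.633 and Itgax at 0.689 ± 0.279.

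The remaining markers gave the same picture. Cd68 (6.46 ± 0.574 TPM), Klrd1 (5.64 ± 1.27) and Pecam1 (6.27 ± 0.304) each led lists whose next members were Csf1r (0.58 ± 0.243), Klre1 (1.19 ± 0.179) and Epcam (0.495 ± 0.176). Trdc was at 1.28 ± 0.29 and Tcrg-C1 at 0.495 ± 0.536. Ly6g (0.491 ± 0.12) and Itga2b (0.461 ± 0.099) led the neutrophil and platelet lists.

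The third comparison asked how far the 4 libraries differed from each other. The largest differences were in sex-linked genes: Eif2s3y, on chromosome Y, was at 0.282 and 0.239 TPM in replicates 1 and 2 and at 65.5 and 58.4 in replicates 3 and 4, and Ddx3y was at 0.428, 0.347, 58.9 and 57.3. Xist, the X-linked RNA that silences an X chromosome and the gene with the largest ratio of all, was at 132, 131, 0.329 and 0.496 TPM. Xist (ENSMUSG00000086503.3) lies on chromosome X from 103460375 to 103483217. Uty and Kdm5d, left out by the filter and chosen with Xist after their values were seen, followed the same order at 0.0838, 0.0553, 7.80 and 8.03 TPM and at 0.0541, 0.0595, 7.33 and 7.16 TPM.

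Otherwise the libraries were close. The BCV was 0.0535, and 0.039 without genes of chromosomes X and Y. Among 8280 genes with a mean of at least 10 TPM, the median coefficient of variation of TPM was 3.64%. Of 12434 genes tested, 216 were called variable by the Poisson deviance with Benjamini-Hochberg adjustment, 188 of them with a mean under 5 TPM. That test allows for counting noise alone and called 101 genes on simulated counts with no changed gene. The stricter test at edgeR's trended dispersion, with the 2-fold ratio kept, left 18 genes. With no ratio asked, it passed 65 genes, 49 of them on autosomes. Leaving out genes of chromosomes X and Y, which lowered the BCV, raised that number to 91. Without replicate 4 the Poisson test called 141. Of the 216 variable genes, only 5 protein-coding ones had a mean of at least 5 TPM. They were Eif2s3y, Ddx3y, mt-Nd6, Serp2 (5.21 ± 2.56 TPM) and the histone gene Hist1h2bk (5.03 ± 1.6). Serp2 and Hist1h2bk did not pass the stricter test. Of the 246 tested genes of the fixed lists, 5 were called by the Poisson test, and only mt-Nd6 of them passed the stricter test. With no ratio asked, the stricter test also passed Il1rn, mt-Co1, mt-Cytb, mt-Nd2, mt-Nd4 and mt-Nd5. Malat1, a nuclear lincRNA also chosen after its values were seen, was at 71.3 TPM in replicate 1 and at 43.6, 51.7 and 43.3 in replicates 2 to 4 (adjusted p = 2.88e-22 by the deviance at edgeR's trended dispersion). The counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 4.09 between replicates 1 and 2 to 11.1 between replicates 1 and 3, so no library was treated as deposited 2 times; this does not show that they came from separate cultures.

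**Figure D3:**
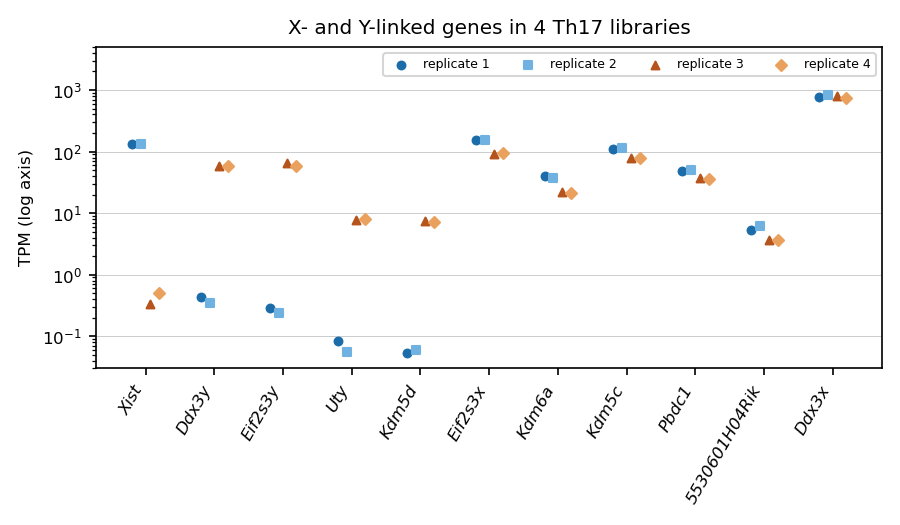
TPM (log axis) of X- and Y-linked genes, 1 point per library. Xist is at 132 and 131 in replicates 1 and 2 and under 1 in replicates 3 and 4, and the 4 Y-linked genes have the opposite order.

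The fourth comparison asked which gene lists varied between libraries. Mitochondrially encoded oxidative phosphorylation genes varied the most, with a median SD of 0.27 in log2 CPM against 0.04 in matched lists. They were low in replicate 1 (median shift -0.27) and replicate 2 (-0.11) and high in replicate 3 (0.34) and replicate 4 (0.07), the division of the replicates seen for Xist and the Y-linked genes. With edgeR's quasi-likelihood test, the split of replicates 1 and 2 from 3 and 4 called 6 of 11 tested mitochondrial genes (7 at an unadjusted p under 0.05), and the other 2 even splits called 0 each (0 and 3). Xist and the Y-linked genes were kept in these fits. In the other 2 splits they add spread within groups, which can lower the calls. Shifts of this list rest on single libraries: without replicate 3 the SD was 0.17, the shift of replicate 1 was -0.17 and that of replicate 2 was 0.00622. Without replicate 1 the shift was -0.22 in replicate 2, 0.22 in replicate 3 and -0.0253 in replicate 4, which was at 0.17 without replicate 3 and, no longer passing, at 0.04 without replicate 2. mt-Co1 was at 8997 TPM in replicate 3, against 7079 ± 1359.7 over the 4 libraries, and mt-Nd4 (969 ± 228) and mt-Nd5 (2221 ± 461) moved with it. mt-Nd6, the tested member encoded on the other strand, did not: it was highest in replicate 1 at 0.68 above its mean log2 CPM and lowest in replicate 2 at -0.60.

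Helper lineage lists shifted by less. Non-pathogenic Th17 genes lay above their means in replicate 2 (median shift 0.09, 7 of 7 members higher) and below them in replicate 4 (-0.10, 7 of 7 lower). In replicate 4, Il9 was at 1377 TPM, Il10 at 112, Ikzf3 at 38.3 and Maf at 129. Il1rn, the IL-1 receptor antagonist, was at 93.2 TPM in replicate 2 against 79.3 ± 9.83 over the 4 libraries. Regulatory T cell genes were also lower in replicate 4 (-0.11, 8 of 11 members lower), with Foxp3 at 3.70 TPM, Itgae at 0.607, Gpr83 at 6.28 and Nrp1 at 5.46. TGF-beta pathway genes were lower in replicate 4 (-0.07, 8 of 10 lower), with Tgfb3 at 0.434 TPM, Tgfbr1 at 72, Smad7 at 28.7 and Smad3 at 55.9. They were higher in replicate 1 (0.05, 9 of 10 higher). Without replicate 4, the shift of non-pathogenic genes in replicate 2 (0.02) and that of TGF-beta genes in replicate 1 (0.02) no longer passed.

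In the same replicate 4, T cell activation genes were higher (0.07, 10 of 12 members), led by Tnfrsf9 at 21.9 TPM, Cd40lg at 181, Nr4a1 at 188 and Tnfrsf4 at 988, and so was glycolysis (0.04, 16 of 16 members), led by Slc16a3 at 28.7, Gapdh at 1530.4, Pfkl at 115 and Tpi1 at 774. T cell activation genes were lower in replicate 2 (-0.04, 9 of 12 members), a shift that did not pass without replicate 4 (-0.02) or without genes of chromosomes X and Y (-0.04). The pathogenic list had all 13 tested members above their means in replicate 4, with a median shift of 0.08 that did not pass (adjusted p = 0.135 by the permutation of lists). Th17 cytokines and receptors were higher in replicate 1 (0.05, 8 of 12) and lower in replicate 3 (-0.05, 10 of 12), where Il1r1 was at 60.9 TPM, Il21 at 312, Il23r at 30.02 and Il17a at 4195. These did not pass without replicate 3 (0.04 in replicate 1) or without replicate 1 (-0.02 in replicate 3). Cholesterol synthesis was lower in replicate 3 (-0.05, 15 of 18), with Mvd and Lss among the members that moved most.

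Of 92 combinations of list and library, these 15 passed an adjusted p of 0.05 by the permutation of lists, with adjusted p from 0.00307 to 0.0294. By the SD between libraries, 7 of 23 lists passed: mitochondrial oxidative phosphorylation, Th17 cytokines and receptors and non-pathogenic Th17 genes (each adjusted p = 0.00153, which rests on 0.0002, the smallest p that the permutation can give), Th1 genes (0.0023), T cell activation (0.00276), follicular helper genes (0.0291) and Th2 genes (0.0302). The member with the largest SD in log2 CPM was mt-Nd6 (0.54) among mitochondrial genes, Il22 (0.27) among Th17 cytokines and receptors, Cxcr3 (0.25) among Th1 genes, Il1rl1 (0.24) among Th2 genes and Tox2 (0.18) among follicular helper genes. Without replicate 4, 2 lists passed for SD and 6 combinations for shift; 6 of the 15 were shifts of replicate 4 itself, which cannot pass without it. The SD then no longer passed for non-pathogenic Th17 genes (0.07), Th1 genes (0.10), Th2 genes (0.12), follicular helper genes (0.06) and T cell activation (0.05). Th1 genes also did not pass without replicate 2 (0.10) or with no filter on low counts (0.16), nor Th2 genes without replicate 1 (0.12). With no filter the Th2 SD (0.26) lay below that of matched lists. Follicular helper genes did not pass with no filter (0.10) or without genes of chromosomes X and Y (0.09). The other 16 lists, with the pathogenic list nearest the threshold at 0.0609, ranged up to an adjusted p of 0.892 by the same permutation.

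**Figure D4:**
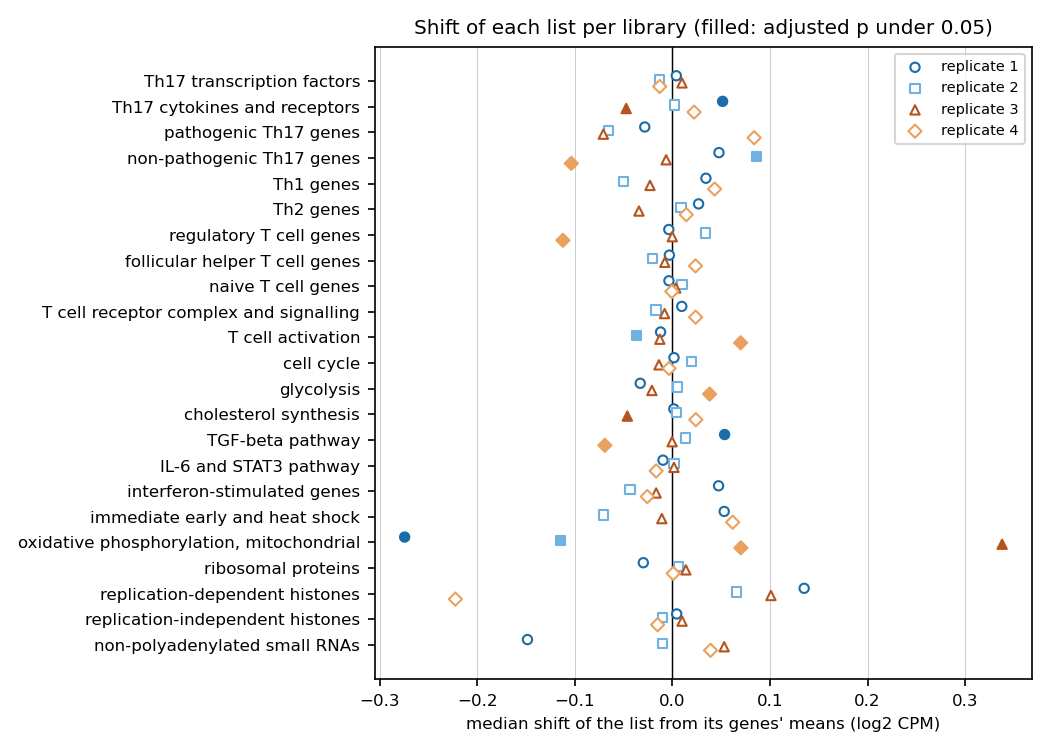
Median shift of each list from its genes' mean log2 CPM in each library; filled points have an adjusted p under 0.05. Mitochondrial genes range from -0.27 in replicate 1 to 0.34 in replicate 3, and all other filled points lie between -0.11 and 0.09.

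The last comparison described what the libraries were made of. Protein-coding genes held 99.1% ± 0.0439 of counts (SD, n = 4), ribosomal protein genes 5.32% ± 0.0511 and the 10 highest genes by CPM 4.83% ± 0.115. Mitochondrially encoded genes held 0.948% ± 0.171, mitochondrial ribosomal RNA 0.0367% ± 0.00296, lincRNA genes 0.267% ± 0.0543, antisense genes 0.052% ± 0.00348, processed pseudogenes 0.109% ± 0.00205, T cell receptor constant genes 0.0448% ± 0.00146, and small nuclear and nucleolar RNA genes 0.00719% ± 0.000197. The mitochondrial share leaves out fragments shared with other genes, which were not counted, so it may be too low. By replicate, 1 to 4, the lincRNA share was 0.33%, 0.294%, 0.219% and 0.224%. Part of that spread is Xist, at 708 and 705 CPM in replicates 1 and 2 against 1.77 and 2.68 in replicates 3 and 4.

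Mitochondrial genes were split. Of 13 protein genes, mt-Co1, mt-Nd1 (6024 ± 955 TPM), mt-Cytb (4431 ± 799.9), mt-Nd2 (3001 ± 493), mt-Nd5, mt-Nd4 and mt-Nd6 (115 ± 45) were counted. In contrast, mt-Atp8 (0.189 ± 0.379), mt-Co2 (0.161 ± 0.202), mt-Atp6 (0.043 ± 0.086) and mt-Co3 (0.0429 ± 0.0506) were near 0, and mt-Nd4l and mt-Nd3 had 0 counts in every library. These 6 were chosen after their values were seen. Except for mt-Atp8, they share 97.6% to 99.9% of their 100-base windows with another annotated gene, and the levels of all 6 are uncertain. Among the counted genes, mt-Nd4 shares 60.8%, mt-Co1 30.8% and mt-Nd2 3.19%, so their levels are uncertain too. The list stood at the 99.94th percentile, a level set by its median member mt-Nd6, and at 24.17 with CPM.

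Histone genes were split as well. Replication-independent histones, whose mRNAs carry poly(A) tails, stood at the 99.5th percentile with H3f3b (917 ± 8.34 TPM), H2afz (529 ± 8.4), H2afx (179 ± 5.03) and H2afy (135 ± 3.09); H2afz shares 58.8% of its windows with another gene, so its level is uncertain. Replication-dependent histones, made in S phase without poly(A) tails, stood at 0.17 with Hist1h1c (9.55 ± 1.54), Hist1h3c (7.84 ± 1.43), Hist1h2ae (6.64 ± 1.08) and Hist1h4d (4.23 ± 1.06) as the highest. Non-polyadenylated small RNAs stood at 0.15, led by the nucleolar RNAs Snora73b (100.04 ± 9.9), Snora73a (25.3 ± 4.11) and Snord17 (17.1 ± 4.35) and by Rpph1, the RNA of RNase P (22.3 ± 1.44). The replication-dependent histones share a median of 25% of their windows with another gene, and the fragments this left uncounted were not measured.

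**Figure D5:**
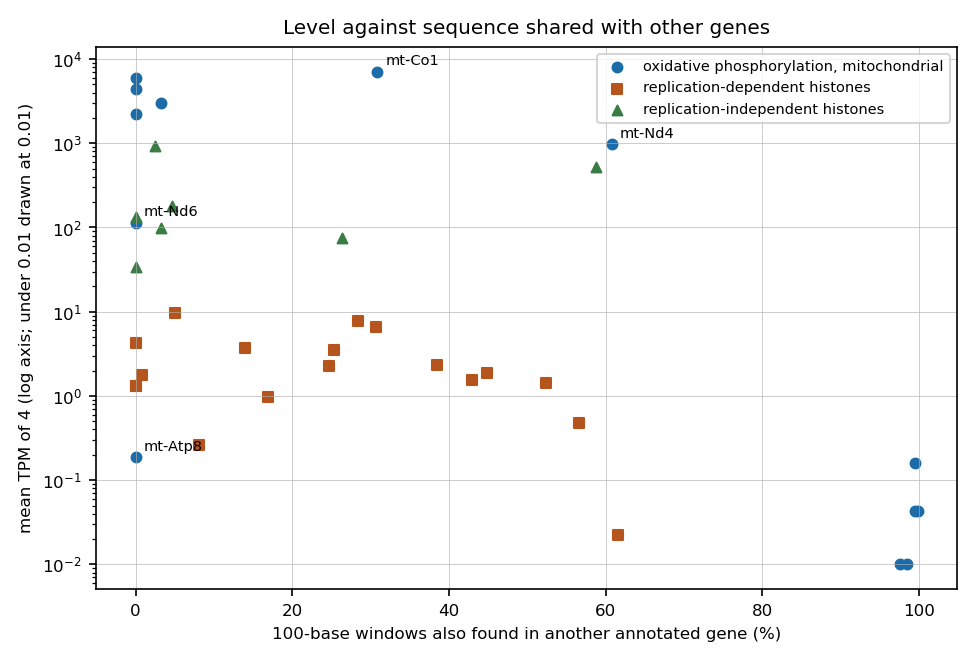
Mean TPM of 4 libraries (log axis; values under 0.01 drawn at 0.01) against the percent of 100-base windows also found in another annotated gene, for mitochondrial and histone genes. Of the near-0 mitochondrial genes, 5 lie above 97% and mt-Atp8 lies at 0%, while replication-dependent histones stay under 10 TPM at every share.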

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

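In 10 of 249 values compared over the 4 libraries, 1 library lay far from the other 3, where chance gives about 1 in 20, or 12.4. Of the genes named here, Cpd and Ccr9 were chosen after their values were seen. Among genes well above the floor, Cpd, a carboxypeptidase, was at 761 TPM in replicate 4 against 828 to 837 in the others. The histone gene H3f3b was at 929 TPM in replicate 1 against 911 to 914. Serp2 was at 9.01 TPM in replicate 4 against 3.55 to 4.42, from 25 to 89 counts per library. Hist1h2ae was at 5.04 TPM in replicate 4 against 7.06 to 7.34, from 28 to 59 counts.

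Low values gave the rest. Col1a1 was at 0.0688 TPM in replicate 2 against 0.179 to 0.188 in the others. Klrk1 at 0.0108 TPM and Mpo at 0.0677 in replicate 4, Hba-a1 at 0.141 in replicate 3 and Ccr9 at 0.0264 in replicate 2 rested on 1, 3, 2 and 3 counts against 0 in every other library. Genes of the nuclear biotype rRNA held 0.000359% of counts in replicate 4 (154 counts, Wilson 95% interval 0.000307 to 0.00042%), against 7e-05 to 7.92e-05% in the others. Ribosomal RNA fragments left uncounted or counted under another biotype are not in that share, so it does not measure the ribosomal RNA of a library. Of the 154, 129 fell on CT010467.1, a gene chosen after its values were seen. As a share of TPM these genes held 0.00197% ± 0.000164 (SD, n = 4), so on that scale the libraries were close.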

How the results depend on the processing

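Of 204 alternatives for the values that answer a comparison, 188 left the value within the spread between replicates, kept its direction, or kept a count within 1.5 times. The 18 gene pairs kept their direction in all alternatives but 1: the gene pair Tcf7/Mki67 turned from 0.35 to -1.59 in CPM, since Mki67 is longer. The between-library dispersion, a BCV of 0.0535, was 0.0568 with no filter, 0.0287 as the median of DESeq2 gene-wise dispersions, 0.039 without genes of chromosomes X and Y, and 0.0531 to 0.0566 with each replicate left out. The 216 variable genes became 1097 with no filter on low counts, which tests more genes, 486 at a ratio of at least 1.5, 18 at the trended dispersion, and 141 to 156 with each replicate left out, which leaves fewer samples. For list variation between libraries, 7 calls became 7, 6, 9 and 2 without replicates 1, 2, 3 and 4, and for list shift per library 15 became 16, 14, 11 and 6; 6 of the 15 are shifts of replicate 4 itself, and beyond that the cause was not tested. Library composition is higher or lower in shares of TPM by construction, since short genes weigh more: 6.17% for the 10 highest genes, 2.5% for mitochondrially encoded genes, 11.5% for ribosomal protein genes and 96.7% for protein-coding genes. Among single lists, the SD of Th2 genes was 0.26 with no filter, below that of matched lists, and with 1 replicate left out the shift of mitochondrial genes ranged from -0.222 to 0.00622 in replicate 2 and from -0.0253 to 0.169 in replicate 4, since the mean they are measured from moves; 17 other alternatives of single lists lost their call. Alternatives based on posterior mean TPM or counts were not run, since the files hold whole-number counts. Depth limits genes under about 0.1 CPM. The alternatives without genes of chromosomes X and Y and without mitochondrial genes were chosen after seeing the data.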

Other observations

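Further cytokine genes were abundant. They were chosen after their values were seen, as were all genes of this paragraph and the next. Lta (lymphotoxin alpha) reached 2864 ± 158 TPM (SD, n = 4), above Il9 and Il2, with Tnf at 607 ± 16.9, the STAT3-activating cytokine Lif at 571 ± 34.9 and the growth factor Pdgfb at 750.5 ± 44.9. Il24 was at 35.9 ± 4.91 and Tnfsf11, which encodes RANKL, at 50.7 ± 4.64. Cd5l, known from non-pathogenic Th17 cells as a regulator of lipid metabolism, was at 237 ± 23, and Pdpn (podoplanin) at 546 ± 40.5.

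Among regulators, Id2 was at 608 ± 43.2 TPM and Id3 at 62.7 ± 12, Bhlhe40 at 395 ± 35.5 and its relative Bhlhe41 at 0.0129 ± 0.0163. Prdm1 (0.611 ± 0.147) and the inhibitory receptor Havcr2 (0.182 ± 0.0574) were under 1 TPM. The proton-sensing receptor Gpr65 was at 299.6 ± 6.62, Il21r at 127 ± 7.08 and Il27ra at 77.4 ± 1.36. In lipid and polyamine metabolism, Odc1 was at 2192 ± 40.3, Scd2 at 611 ± 54.1, Fasn at 252 ± 8.28 and Scd1 at 30.5 ± 5.94. The gut-homing genes Itgb7 (54.2 ± 2.27) and Ccr9 (0.0066 ± 0.0132) stood far apart.

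With no filter on low counts, the highest library among the 1097 genes called by the Poisson deviance was replicate 1 for 254, replicate 2 for 216, replicate 3 for 183 and replicate 4 for 444; the cause was not tested.

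For the patterns weighed next, the tests of depth, of X-linked genes, of gene length, of cell division, of poly(A) selection, of the separation of autosomal genes and of the separate parts of a pattern were chosen after the result was seen. The tests of the even splits and of shared sequence were chosen before their results were seen.

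Xist was high in replicates 1 and 2 and Y-linked genes in replicates 3 and 4, although all 4 libraries carry the same donor label. A difference in depth is argued against. Replicates 1 and 3 had the lowest and highest totals, 28555677 and 58104663 counts. Their Xist counts were 20217 and 103, and their Eif2s3y counts 10 and 4769, differences far beyond that in totals. With every library drawn down to 28555677 counts, the ratio of the highest to the lowest Xist count was 374. Such a draw keeps each gene's expected share, so that ratio could hardly have fallen. Cells from animals of different sex are a candidate explanation, since 5 of 6 X-linked genes known to escape inactivation (Kdm6a, Kdm5c, Eif2s3x, Pbdc1 and 5530601H04Rik, the exception being Ddx3x) had both values in replicates 1 and 2 above both in replicates 3 and 4. A wider difference between these pairs of replicates is argued against as the whole cause: with no filter on low counts and values under 3 counts raised to 3, no autosomal gene separated the pairs by more than 3.60-fold (3.77 and 4.32 in the other 2 even splits), while Xist, Ddx3y, Eif2s3y, Uty and Kdm5d each did so by at least 93.8-fold. A smaller difference beside it stays open. With edgeR's quasi-likelihood test, that split called 13 autosomal genes at an adjusted p under 0.05 (784 at an unadjusted p under 0.05). The other 2 even splits called 0 each (437 and 453), with 6 of 11 mitochondrial genes against 0 each. These counts cannot decide it. Xist and the Y-linked genes were kept in all 3 fits, and in the other 2 splits they add spread within groups, which can lower the calls. Leaving out genes of chromosomes X and Y lowered the BCV over the 4 libraries from 0.0535 to 0.039. With 3 possible splits, moreover, no share under 0.05 can be reached.

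Of the mitochondrial protein genes, 6 were near 0 beside others between 115 and 7079 TPM. Gene length is argued against as the cause for mt-Co2, mt-Atp6 and mt-Co3, because the shorter mt-Nd6 was counted at 115 TPM. For mt-Nd3, mt-Nd4l and mt-Atp8 gene length stays open, since they are shorter than every counted gene. Fragments shared with other annotated genes and left uncounted are a candidate explanation: the 6 genes share a median of 99% of their 100-base windows with other genes, such as mt-Co2 with Gm28661 and mt-Co3 with Gm28437, against a median of 0% for the 7 counted genes, of which mt-Nd4 shares 60.8%, mt-Co1 30.8% and mt-Nd2 3.19%. For mt-Atp8 it stays open, since it shares 0% of its windows, but 43 of its 204 bases overlap mt-Atp6, which the windows do not read. No biological explanation was tested.

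Replication-dependent histones had a median of 1.84 TPM, against 135 for replication-independent ones. Few dividing cells are argued against as the cause, since the cell cycle list stood at the 100th percentile. Shared sequence does not settle it for the list as a whole, with a median of 25% of windows shared. For the 6 members that share under 10% it is argued against, because their median was 1.55 TPM. That share is taken over the longest transcript, so it can be low although a part is shared. Hist1h2ac shares 192 of 2383 windows, while Hist1h1b, Hist1h1a and Hist1h4d share 0. Selection of poly(A)-tailed RNA, which the linked protocol names, is a candidate explanation: Rn7sk, Rmrp and Rpph1, abundant RNAs without poly(A) tails chosen with their test, had a median of 6.5 TPM, below that of the replication-independent histones. Sequence that these RNAs share with other genes was not measured, and shared fragments were left uncounted. Their low level therefore cannot tell poly(A) selection from uncounted fragments. No biological explanation beyond cell division was tested.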
